A study of Homo sapiens with 8 samples.

How the data were processed

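Per the labels' protocols, RNA was collected in TRIzol, 1 µg of it entered each library, and libraries were made with the NEBNext Ultra RNA kit. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used; their options and the order of other steps are not given in the sources used here. Poly(A) selection, read length and strand setting are not given in the sources used here. The values are FPKM, fragments per kilobase of gene length scaled to library size, as deposited by the authors for each of the 8 libraries with the gene lengths used. The genome build is not stated, but the coordinates of all 58735 genes in the deposited table are identical to those of GENCODE 29 on GRCh38, so that build is given with positions. Columns were matched to samples by name, and 0 columns of per-sample values were left without a sample.

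Depth was read from the values. In each library FPKM times gene length is a whole multiple of the smallest non-zero product, taken as 1 read, within a tolerance of 0.01, for 99.92 to 99.98% of non-zero values, which gives 15632154 to 19148262 reads per library. The denominators that the authors used differ from these totals, at 1.18 to 1.20 times the reads in HepaRG plate, 0.968 to 1.19 times in M14A plate and 0.818 and 0.853 times in printed cells. They follow median-ratio size factors computed from the recovered reads within 0.979 to 1.03 times, so the deposited FPKM carry a scaling of that kind and their totals differ between libraries, from 254141 to 514152. A change in a gene is therefore a change relative to the bulk of genes in the library, and a shift shared by most genes cannot be seen on this scale. For a gene of 1 kb, 1 read equals 0.0435 to 0.0747 FPKM. Genes with exons in other genes, and near-identical copies, can lose or share reads in gene counting, and reads of antisense partners cannot be told apart without strand.

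Groups were taken from the sample titles. Genes with at least 1 FPKM in at least 2 libraries were tested (14349, of which 11306 are protein-coding), as log2(FPKM + 1), with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), all 8 libraries in 1 fit with 3 group means and 5 residual degrees of freedom. Both comparisons share the M14A plate libraries and are not set against each other. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested; all tests are two-sided, and calls of at least 2-fold were counted beside. The 2 printed libraries give little information on their own spread, which is taken from all groups. A set of 25 gene lists with 356 entries, 275 of them tested, was fixed before the data were examined, as were the tests, the comparisons and the first set of alternative settings. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The estimated form also uses only the 5 residual degrees of freedom, so its p-values can rise without a higher correlation. For hepatocyte secreted proteins in printed cells, at an estimated correlation of 0.0112, the unadjusted camera p went from 1.3e-04 to 0.013. Calls of members are given over all genes and adjusted over the list alone. Named genes are FOXM1 and HNF4A, the 5 protein-coding genes with the largest rise and the 5 with the largest fall among called genes whose groups did not overlap, and from each list up to 2 called members with the largest change, or the member with the highest mean where none was called. Some genes that this rule selects are not reported here. ALB and PMAIP1 in the comparison of the flask-grown lines, MT-ND5, ATF3, NR4A1, JUNB, DUSP1 and KLF6 in that of printed cells, and the genes named under other observations were chosen after their values were seen. Replicates of a group were compared by a chi-square per degree of freedom over recovered reads, which was 3.13 to 93.3 for the 7 pairs, so no library was counted as a duplicate.

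Alternatives were pseudocounts of 0.1 and 0.01, no filter and a filter at 5 FPKM, median-ratio, quantile, equal-total and equal-total scaling without mitochondrial genes, a fit of only the groups compared, eBayes without trend, voom weights on the recovered reads, the replicate number as a block, each library left out, and a threshold of 0.01. After the data were seen, 3 were added: removal of each library's trend with transcript GC content and gene length by natural splines with 5 degrees of freedom, the same without M14A plate library 1, and protein-coding genes only. GC content was the median over a gene's GENCODE 29 transcripts, and 12 tested genes had none. The procedure was tested on simulated reads drawn with the real means and denominators and 200 changed genes. For M14A plate minus HepaRG plate it called 75% of 2-fold and 98% of 4-fold changes, and 15 unchanged genes among 13617 tested. For M14A printed minus M14A plate it called 63% and 100.0%, and 11 among 13660. The simulated reads had the same dispersion of 0.0254 for both comparisons, while real replicate pairs differed widely in spread (chi-square per degree of freedom 3.13 to 93.3). These shares hold for the simulated reads and may not hold for the real libraries.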

Results

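RNA sequencing compared a human hepatic cell line, a gene-edited derivative of it, and that derivative after bioprinting. HepaRG is a human bipotent hepatic progenitor line that can be grown into hepatocyte-like and biliary-like cells. M14A is HepaRG with edited genes, and its genotype label names FOXM1 and HNF4A as transfected. The samples formed 3 groups. HepaRG plate (3 libraries) and M14A plate (3 libraries) were grown in culture flasks. M14A printed (2 libraries) was mixed into a bioink called GP, printed, and collected 4 h later. Printed constructs were frozen in liquid nitrogen and ground before RNA extraction, while flask cells were detached and pelleted, so printing and the way of collection differed together. Expression was given as FPKM for 58735 annotated genes, and 15632154 to 19148262 reads per library were recovered from the values. The share of reads from all mitochondrially encoded genes, ribosomal RNA included, was 6.91 to 7.25% in HepaRG plate, 8.21 to 9.72% in M14A plate, and 13.3 and 16.4% in the printed libraries. M14A plate library 1 stood apart from libraries 2 and 3 of its group. Its Pearson correlations with them across genes were 0.957 and 0.948, against 0.988 between those libraries. Nothing in the labels says that replicates came from separate cultures, so all p-values measure only the spread between these samples, which may be technical. Below, levels are mean FPKM ± SD (n = 3 for plate groups, n = 2 for printed cells). Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and carry their SE and the Benjamini-Hochberg adjusted p of limma.

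The 2 genes named in the genotype label were examined in every library. HNF4A is a nuclear receptor that drives hepatocyte identity (ENSG00000101076, chromosome 20, 44355700 to 44434596 on GRCh38). It stood at 5.67, 6.24 and 6.50 FPKM in the HepaRG libraries and at 37.9, 43.1 and 41.7 FPKM in the M14A plate libraries. HNF4A was higher in M14A plate than in HepaRG plate (log2 fold change 2.55, SE 0.13, adjusted p = 2.7e-06). In printed cells it stood at 17.1 and 13.6 FPKM, lower than in M14A plate (log2 fold change -1.36, SE 0.15, adjusted p = 7.2e-04) and above each HepaRG library. FOXM1 is a transcription factor of the G2 and M phases (ENSG00000111206, chromosome 12, 2857681 to 2877155). It was not higher in the M14A libraries, averaging 13.8 ± 0.991 FPKM in HepaRG plate, 10.8 ± 2.06 in M14A plate and 10.1 ± 0.0594 in printed cells. Its difference between the flask-grown lines did not pass the test (log2 fold change -0.34, SE 0.15, 95% interval -0.68 to -0.01, adjusted p = 0.11). It passed with a log2 fold change of -0.48 when M14A plate library 1 was left out, and under 6 other settings, each time with the lower value in M14A. Between printed and plate M14A cells the log2 fold change of FOXM1 was -0.07 (SE 0.16), with an adjusted p of 0.77. At equal FPKM totals, which shift all genes of a library alike, it passed at -0.75, and at equal totals without mitochondrial genes at -0.59 (adjusted p = 6.3e-04 and 0.0031). Reads of an introduced coding sequence count toward either gene only where they fall in its annotated exons.

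**Figure D1:**
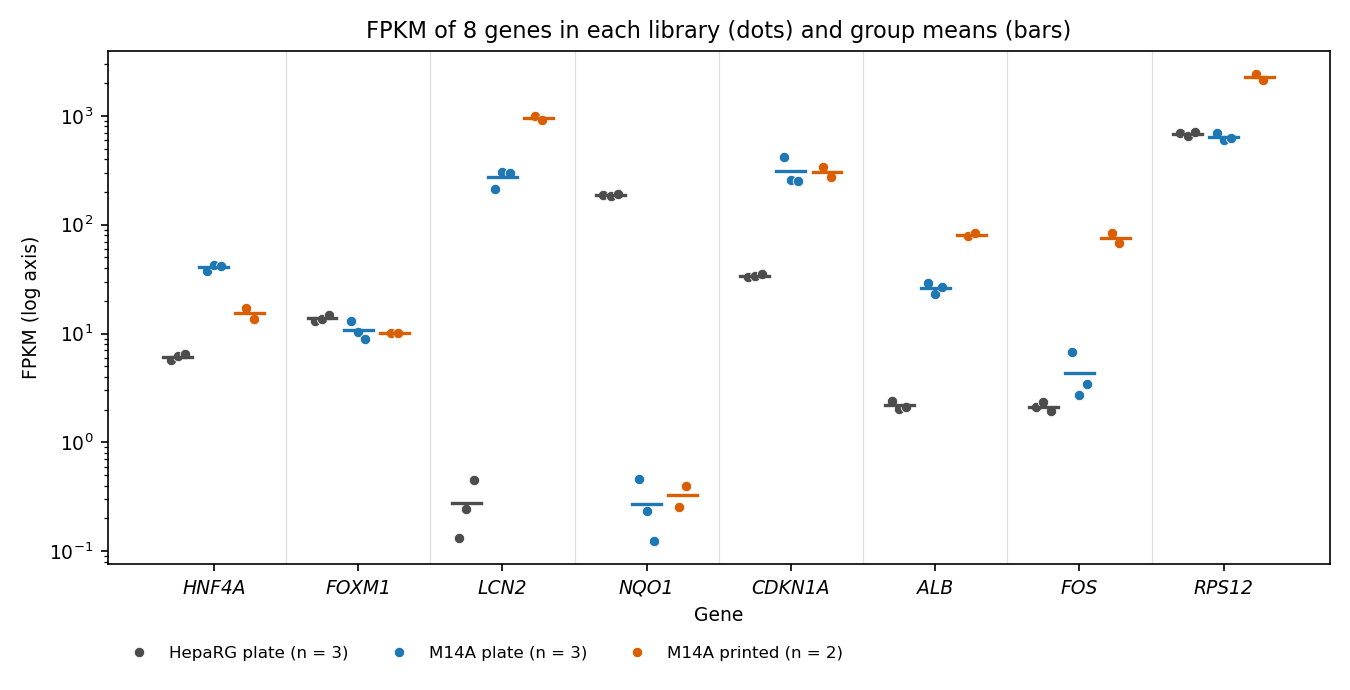
FPKM on a log axis (vertical) of 8 genes (horizontal) in each library, as dots, with short bars for the mean of each group: HepaRG plate (3 libraries), M14A plate (3) and M14A printed (2). HNF4A was highest in M14A plate, LCN2 lay below 1 FPKM in HepaRG and above 200 FPKM in every M14A library, NQO1 lay below 1 FPKM in every M14A library, and FOS and RPS12 were highest in the printed libraries.

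The comparison of M14A plate with HepaRG plate asks how the edited line differs from its parent under the same culture. M14A cells carried far more RNA of liver-secreted plasma proteins, of inflammatory genes and of p53 targets than HepaRG cells, and less RNA of NRF2 targets. The largest rise was in LCN2, a lipocalin of the acute phase that binds bacterial siderophores, from 0.275 ± 0.160 to 271 ± 51.7 FPKM (log2 fold change 7.73, SE 0.17, adjusted p = 4.1e-08). The largest fall was in NQO1, a quinone reductase induced by NRF2, from 187 ± 3.16 to 0.274 ± 0.172 FPKM (log2 fold change -7.21, SE 0.13, adjusted p = 2.0e-08). Next among the rises, the pentraxin APCS went from 0.801 ± 0.214 to 91.8 ± 15.2 FPKM, and the water and glycerol channel AQP9 from 1.35 ± 0.161 to 105 ± 22.0 FPKM. PDZK1IP1, which encodes a small membrane protein, rose from 12.6 ± 1.25 to 577 ± 30.1 FPKM, and the chemokine CXCL1 from 2.52 ± 0.264 to 172 ± 21.03 FPKM. Their log2 fold changes were 5.68 (SE 0.16), 5.48 (SE 0.17), 5.41 (SE 0.13) and 5.62 (SE 0.14). After NQO1, the cancer-testis gene MAGEC2 fell from 65.8 ± 0.743 to 0.0742 ± 0.0218 FPKM, and the hair keratin gene KRT81, which has close paralogs, from 33.3 ± 2.70 to 0.0961 ± 0.0291 FPKM. The fibrillar collagen gene COL5A1 fell from 25.04 ± 1.12 to 0.0121 ± 0.0139 FPKM, and TMPRSS15, which encodes enteropeptidase, from 23.9 ± 0.365 to 0.0958 ± 0.0636 FPKM. Their log2 fold changes were -5.96 (SE 0.10), -4.96 (SE 0.11), -4.68 (SE 0.099) and -4.51 (SE 0.10). The adjusted p of these 10 genes lay between 2.0e-08 and 2.3e-07. Only called genes whose groups did not overlap could be named here, so their passing and their separation follow from the selection.

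Of 13 tested hepatocyte secreted proteins, 10 rose and 0 fell (11 and 0 adjusted over the list alone). Camera gave the list an adjusted p of 1.8e-08, and adjusted p = 0.021 with an estimated correlation. The fibrinogen chain FGB rose from 2.11 ± 0.280 to 120.4 ± 26.6 FPKM (log2 fold change 5.26, SE 0.19, adjusted p = 4.3e-07). The protease inhibitor SERPINA1 rose from 9.55 ± 0.837 to 334 ± 109 FPKM (log2 fold change 4.94, SE 0.21, adjusted p = 1.0e-06). Albumin (ALB) rose from 2.19 ± 0.211 to 26.3 ± 3.01 FPKM. Of 13 NF-kappaB and acute phase genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone). Here the camera adjusted p was 1.3e-12, and adjusted p = 0.012 with an estimated correlation. Beside CXCL1, the chemokine CCL20 rose from 0.683 ± 0.167 to 57.4 ± 9.01 FPKM (log2 fold change 5.11, SE 0.16, adjusted p = 1.7e-07). Of 14 p53 and DNA damage genes, 11 rose and 1 fell (12 and 2 adjusted over the list alone). By camera the adjusted p was 7.5e-06, and adjusted p = 0.021 with an estimated correlation. The cell cycle inhibitor CDKN1A rose from 34.0 ± 1.10 to 311 ± 95.2 FPKM (log2 fold change 3.12, SE 0.20, adjusted p = 1.1e-05). The mitochondrial ferredoxin reductase FDXR rose from 6.68 ± 0.539 to 61.9 ± 26.0 FPKM (log2 fold change 2.96, SE 0.27, adjusted p = 6.5e-05). The member that fell was PMAIP1, a pro-apoptotic p53 target, from 14.7 ± 1.07 to 6.93 ± 1.40 FPKM. Of 12 oxidative stress (NRF2) genes, 0 rose and 10 fell (0 and 10 adjusted over the list alone). For this list the camera adjusted p was 3.5e-06, and adjusted p = 0.021 with an estimated correlation. Beside NQO1, the cystine transporter SLC7A11 fell from 28.3 ± 1.70 to 1.88 ± 0.880 FPKM (log2 fold change -3.40, SE 0.23, adjusted p = 1.2e-05).

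Of 19 G2/M genes including FOXM1 targets, 0 rose and 10 fell (0 and 11 adjusted over the list alone). The camera adjusted p was 0.0019, but adjusted p = 0.056 with an estimated correlation. Topoisomerase TOP2A fell from 44.1 ± 1.94 to 18.5 ± 7.18 FPKM (log2 fold change -1.29, SE 0.27, adjusted p = 0.0075). The kinetochore gene CENPF fell from 15.1 ± 0.523 to 5.67 ± 1.07 FPKM (log2 fold change -1.28, SE 0.15, adjusted p = 3.1e-04). Of 15 hypoxia and glycolysis genes, 11 rose and 2 fell, the same as adjusted over the list alone. By camera the adjusted p was 0.0057, but adjusted p = 0.61 with an estimated correlation. Carbonic anhydrase CA9 rose from 4.10 ± 0.388 to 51.3 ± 18.6 FPKM (log2 fold change 3.31, SE 0.24, adjusted p = 2.1e-05), and 38.5% of its exon bases lie in exons of another gene. The stress-response gene NDRG1 rose from 4.69 ± 0.184 to 26.3 ± 17.7 FPKM (log2 fold change 2.08, SE 0.35, adjusted p = 0.0025). It stood at 46.6 FPKM in M14A plate library 1 and at 16.8 and 15.3 FPKM in libraries 2 and 3. Of 13 immediate early genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The camera adjusted p was 0.0058, but adjusted p = 0.61 with an estimated correlation. The zinc finger factor EGR1 rose from 3.67 ± 0.268 to 20.8 ± 9.41 FPKM and the early response gene IER3 from 25.6 ± 0.819 to 65.6 ± 28.4 FPKM, both with their highest plate value in M14A plate library 1. Of 7 replication-dependent histone genes, 4 rose and 0 fell, the same as adjusted over the list alone. Camera gave them an adjusted p of 0.036, but adjusted p = 0.45 with an estimated correlation. HIST2H2BE rose from 2.92 ± 0.172 to 8.07 ± 0.981 FPKM, and the linker histone gene HIST1H1C from 38.8 ± 1.63 to 85.5 ± 11.6 FPKM. Histone messages of this class mostly lack a poly(A) tail. The list lost its call without M14A plate library 1 (camera adjusted p = 0.059), with the length and GC trend removed (0.17) and with both (0.13).

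Among lists with no call, liver functions moved in both directions. Of 10 drug metabolism enzymes 4 rose and 2 fell (camera adjusted p = 0.55). The glucuronosyltransferase UGT2B7 rose from 0.0855 ± 0.0752 to 4.94 ± 0.228 FPKM, and the glutathione transferase GSTA1 fell from 29.2 ± 2.79 to 6.55 ± 1.32 FPKM. Both belong to families of similar genes, so their values are uncertain. Of 8 genes of bile acid synthesis and transport 5 rose and 1 fell (camera adjusted p = 0.13). HSD3B7, an enzyme of bile acid synthesis, rose from 1.32 ± 0.332 to 3.86 ± 0.735 FPKM, although 64.7% of its exon bases lie in another gene. The bile acid receptor NR1H4 had 0 reads in the HepaRG libraries and 0.954 ± 0.495 FPKM in M14A plate, at least 72.4-fold higher than a floor of 3 reads over the HepaRG group. Of 6 genes of the urea cycle and ammonia handling 2 rose and 1 fell (camera adjusted p = 0.51). The aspartate-glutamate carrier SLC25A13 rose from 14.2 ± 0.999 to 27.7 ± 3.99 FPKM, and the carbamoyl phosphate synthetase CPS1 fell from 2.50 ± 0.236 to 1.02 ± 0.224 FPKM. Of 3 gluconeogenesis and glycogen genes 1 rose and 2 fell (camera adjusted p = 0.57). The coactivator PPARGC1A fell from 7.89 ± 0.699 to 3.95 ± 1.27 FPKM (log2 fold change -0.88, SE 0.21, adjusted p = 0.014), a call lost without HepaRG plate library 2 (log2 fold change -0.81). The carboxykinase PCK2 fell from 21.3 ± 0.765 to 13.2 ± 3.62 FPKM, a call lost without HepaRG plate library 1, 2 or 3 (log2 fold change -0.70, -0.68 and -0.66) or M14A plate library 2 or 3 (-0.59 and -0.57). Of 10 liver transcription factors other than HNF4A, 2 rose and 2 fell (camera adjusted p = 0.66), with a median log2 fold change of -0.12 and a mean of 0.19. The xenobiotic receptor NR1I2 rose from 0.350 ± 0.0568 to 2.65 ± 0.307 FPKM (log2 fold change 1.43, SE 0.11, adjusted p = 2.9e-05). The counts adjusted over the list alone were the same for these 5 lists.

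Progenitor, mesenchymal and adhesion genes also went both ways without a list call in the main fit. Of 8 biliary and progenitor markers 2 rose and 3 fell, the same as adjusted over the list alone (camera adjusted p = 0.12). The surface glycoprotein CD24 fell from 18.8 ± 0.807 to 0.509 ± 0.315 FPKM, and osteopontin (SPP1) from 52.6 ± 0.579 to 9.65 ± 1.47 FPKM. Of 14 extracellular matrix and mesenchymal genes 3 rose and 7 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.12). After COL5A1 the largest fall among them was in the matricellular protein SPARC, from 5.89 ± 0.168 to 0.0251 ± 0.0347 FPKM. Of 15 adhesion and YAP target genes 2 rose and 5 fell, the same as adjusted over the list alone (camera adjusted p = 0.30). Thrombospondin THBS1 fell from 44.6 ± 1.95 to 4.91 ± 0.791 FPKM, and the actin crosslinker FLNA from 128 ± 5.82 to 22.0 ± 4.24 FPKM. Of 7 stellate cell and fibroblast markers 3 rose and 2 fell, the same as adjusted over the list alone (camera adjusted p = 0.12). The mucin-like PDPN rose from 4.89 ± 0.112 to 39.7 ± 1.06 FPKM, and the proteoglycan decorin (DCN) from 3.15 ± 0.217 to 27.9 ± 10.1 FPKM. The only endothelial marker tested, KDR, rose from 0.545 ± 0.0918 to 1.42 ± 0.158 FPKM. Both leukocyte markers tested rose, LAPTM5 from 0.768 ± 0.0693 to 4.40 ± 0.943 FPKM and CD14 from 1.71 ± 0.2503 to 3.55 ± 1.27 FPKM. The call of CD14 was lost without HepaRG plate library 1 or 2 (log2 fold change 0.71 and 0.65). The counts of these marker lists were the same as adjusted over the list alone. Some lists passed under another filter: biliary and progenitor markers as lower at 5 FPKM (0.0022) and with no filter (0.023), matrix genes as lower with no filter (0.0079), and stellate markers as higher at 5 FPKM (0.0017). In the main fit with an estimated correlation the adjusted p of these 3 lists was 0.38, 0.45 and 0.38.

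Of 12 endoplasmic reticulum stress genes 4 rose and 3 fell, the same as adjusted over the list alone (camera adjusted p = 0.70). The stress factor ATF4 fell from 126 ± 2.23 to 50.3 ± 11.2 FPKM, and its target CHAC1 from 6.76 ± 1.01 to 2.42 ± 0.797 FPKM. Of 14 sterol synthesis genes 0 rose and 3 fell, the same as adjusted over the list alone (camera adjusted p = 0.57), around a median of 0.00 and a mean of -0.15. The synthase HMGCS1 fell from 35.2 ± 0.769 to 13.1 ± 3.01 FPKM. Of 17 DNA replication genes 1 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 0.70). The helicase subunit MCM5 fell from 21.8 ± 0.379 to 8.78 ± 1.57 FPKM. Thymidylate synthase TYMS rose from 21.4 ± 1.29 to 35.4 ± 6.45 FPKM, with 46.6% of its exon bases in other genes. Of 13 heat shock genes 0 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 0.51). It was the cochaperone CHORDC1 (log2 fold change -0.71, SE 0.16), with a call lost without HepaRG plate library 1 (-0.66). Of 13 mitochondrially encoded genes 4 rose and 0 fell, the same as adjusted over the list alone (camera adjusted p = 0.078, but adjusted p = 0.63 with an estimated correlation). This list passed with either or both printed libraries left out of the fit (0.049 each) and with no filter (0.0053). Of its rises, MT-ATP6 was not called without HepaRG plate library 1, 2 or 3 (log2 fold change 0.60, 0.58 and 0.68), and MT-ND6 without HepaRG plate library 1 (0.46). Of 16 cytosolic ribosomal protein genes 0 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.70). This gene was RPS23 (log2 fold change -0.86, SE 0.26), and its call was lost with any library other than M14A plate library 2 left out.

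**Figure D2:**
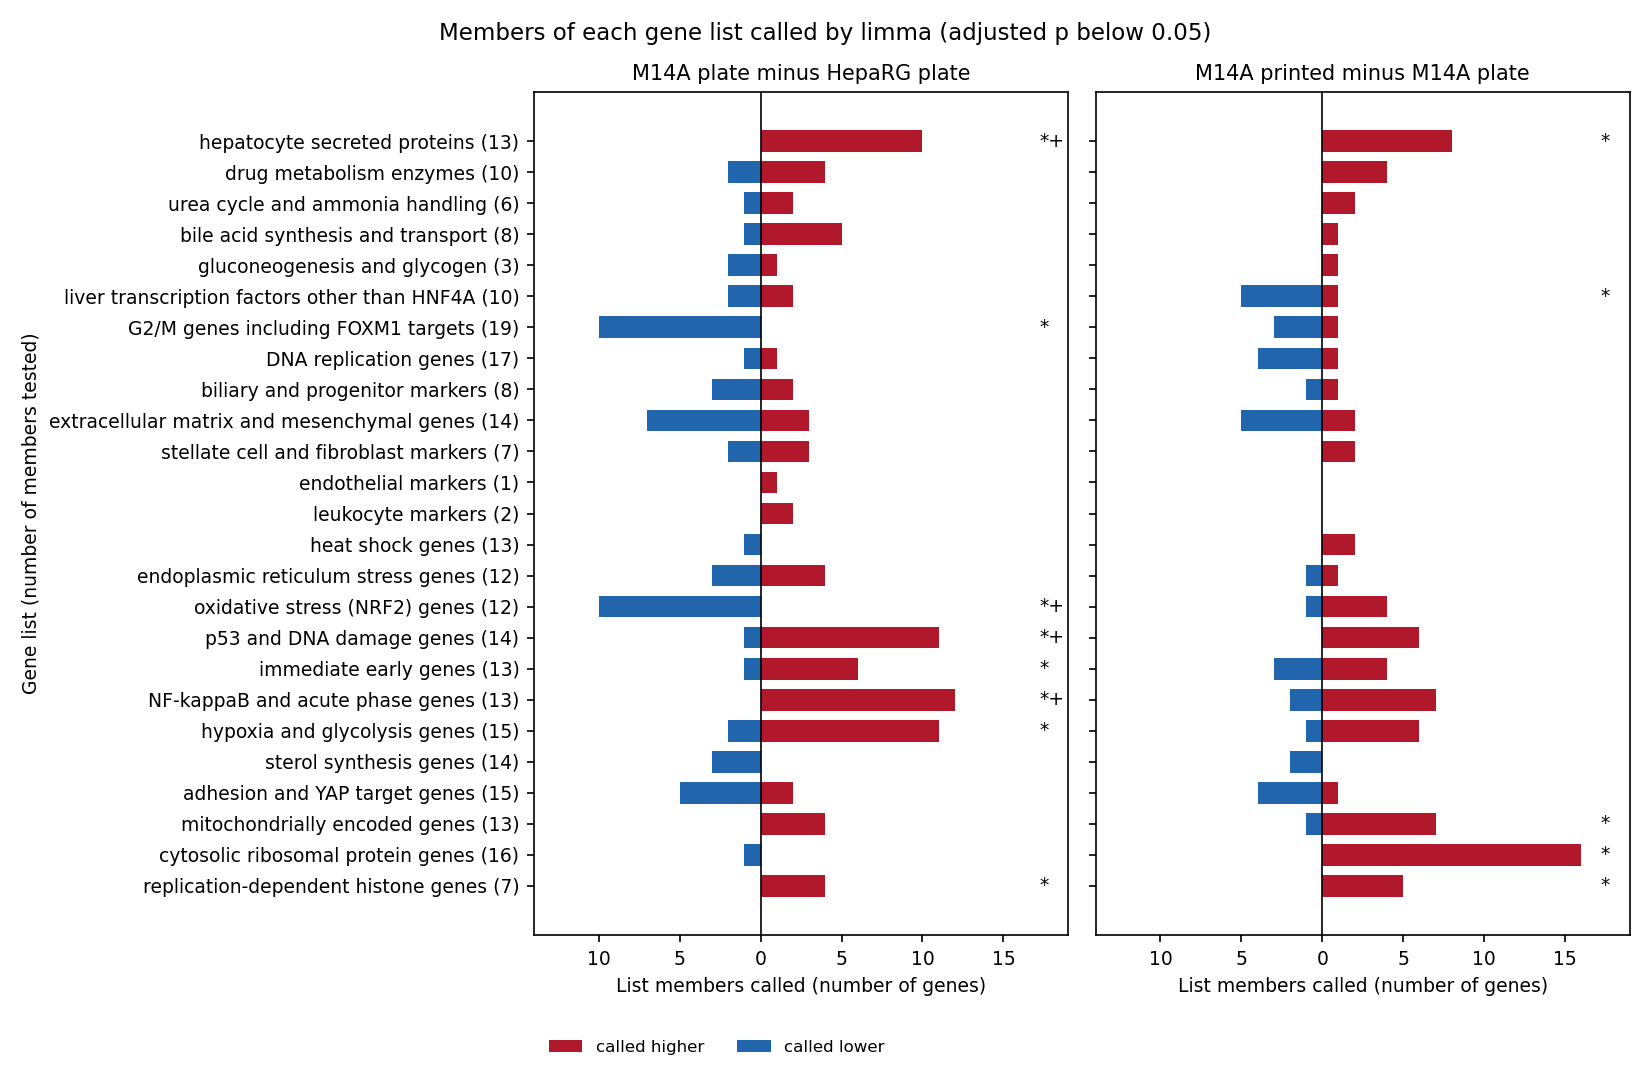
Number of members called higher (red, to the right of 0) and lower (blue, to the left) in each fixed gene list (vertical axis, members tested in brackets), for M14A plate minus HepaRG plate (left) and M14A printed minus M14A plate (right), with * for a list called by camera and + for a call that held with an estimated correlation. All 10 NRF2 calls were falls in the left panel, and all 16 ribosomal protein genes were called higher in the right panel.

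Over all 14349 genes tested, 2317 were higher and 2112 lower in M14A plate than in HepaRG plate, and 950 and 597 of these by at least 2-fold. Camera was run on 23 lists, of which 6 were called higher and 2 lower. With an estimated correlation 4 calls held: hepatocyte secreted proteins, NF-kappaB and acute phase genes, p53 and DNA damage genes, and NRF2 genes. Without M14A plate library 1 the counts of genes were 2912 and 3220, and without HepaRG plate library 1, 2 or 3 the lower count was 1252, 1262 and 1261. Rescaling each library to an equal FPKM total moved the median log2 fold change of all genes from -0.04 to -0.20 and the share of higher genes among calls from 52.3 to 37.9%. At equal totals without mitochondrial genes that median was -0.14.

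The comparison of printed with plate M14A cells asks how the cells differed 4 h after being mixed into bioink and printed. Printed cells held more RNA of the immediate early genes FOS and FOSB, of cytosolic ribosomal proteins and of several secreted liver proteins, and less RNA of HNF4A and of several other liver transcription factors. The list calls for ribosomal proteins, secreted proteins and liver transcription factors were lost with an estimated correlation (adjusted p = 0.37, 0.29 and 0.58), and the immediate early list, with 4 rises and 3 falls, was not called. FOS, a subunit of the AP-1 factor that responds rapidly to stimuli, rose from 4.33 ± 2.14 to 76.1 ± 10.7 FPKM (log2 fold change 3.92, SE 0.28, adjusted p = 3.6e-04). Its relative FOSB rose from 0.141 ± 0.0675 to 8.34 ± 1.81 FPKM (log2 fold change 3.02, SE 0.15, adjusted p = 2.1e-04). HSPA6, a stress-inducible heat shock protein, rose from 0.371 ± 0.298 to 6.95 ± 2.25 FPKM (log2 fold change 2.53, SE 0.23, adjusted p = 5.3e-04). The largest falls were in long genes, of 10470 to 20485 exonic bases. The beta-catenin cofactor BCL9L fell from 22.4 ± 6.06 to 3.62 ± 1.27 FPKM, and 38.8% of its exon bases lie in other genes. The histone methyltransferase KMT2D fell from 7.83 ± 1.48 to 0.746 ± 0.00290 FPKM, and perlecan (HSPG2) from 58.7 ± 6.61 to 11.3 ± 4.45 FPKM. The cytoskeletal linker plectin (PLEC) fell from 83.7 ± 18.4 to 17.5 ± 9.97 FPKM, and TNRC18 from 19.5 ± 4.75 to 3.33 ± 1.62 FPKM. Log2 fold changes of these 5 genes lay between -2.34 and -2.27, and their adjusted p between 3.6e-04 and 0.0015. The cancer-testis genes GAGE12C (log2 fold change 4.71, SE 1.204, adjusted p = 0.018) and GAGE13 (log2 fold change 2.18, SE 0.68, adjusted p = 0.038) also passed the test. They belong to a family of near-identical copies and are uncertain, and GAGE12C stood at 280.2 and 6.55 FPKM in the printed libraries. GAGE13 lost its call without printed library 1 or 2 (log2 fold change 1.76 and 2.61), M14A plate library 2 or 3 (1.90 and 2.31) or HepaRG plate library 2 (2.18).

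Across 11296 protein-coding genes, the log2 fold change went down with gene length (Spearman's rho -0.43 across genes, which are not independent replicates). Its median was 0.45 in the shortest quintile and -0.26 in the longest, and rho with GC content was -0.09. For M14A plate minus HepaRG plate, rho was -0.20 with length and 0.30 with GC. M14A plate library 1 differed from libraries 2 and 3 with a rho of 0.74 with GC.

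**Figure D3:**
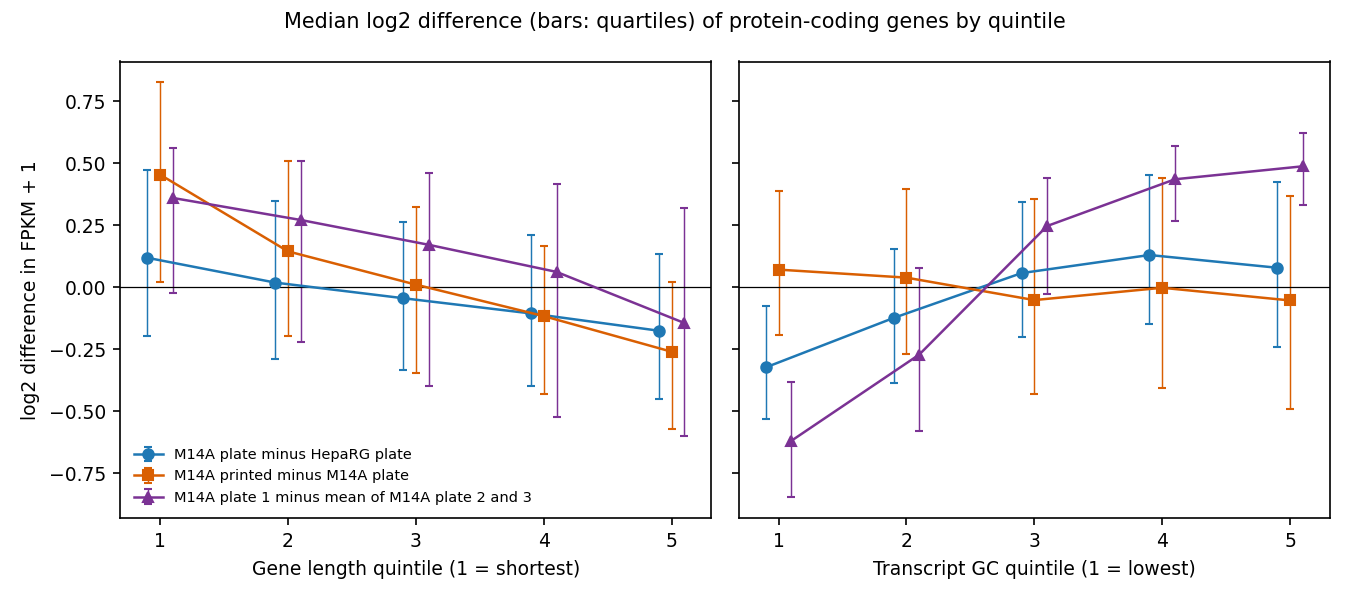
Median log2 difference in FPKM + 1 (vertical axis, bars from the lower to the upper quartile) of protein-coding genes in quintiles of gene length (left) and of transcript GC content (right), for M14A plate minus HepaRG plate, M14A printed minus M14A plate, and M14A plate library 1 minus the mean of libraries 2 and 3. The printed difference went from 0.45 in the shortest to -0.26 in the longest quintile, and library 1 went from -0.62 in the lowest to 0.49 in the highest quintile of GC.

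All 16 cytosolic ribosomal protein genes tested rose, also when adjusted over the list alone, with a median log2 fold change of 1.37. The camera adjusted p was 4.4e-11, but adjusted p = 0.37 with an estimated correlation. RPS12 rose from 641 ± 46.3 to 2277 ± 202 FPKM (log2 fold change 1.83, SE 0.13, adjusted p = 3.6e-04), and RPL32 from 149 ± 21.7 to 429 ± 44.6 FPKM (log2 fold change 1.53, SE 0.16, adjusted p = 6.5e-04). Ribosomal protein genes have many pseudogene copies that can share reads. Their messages are short, but gene length here counts all exonic bases, 767 for RPS12 and 5894 for RPS3. With the trend of each library in gene length and GC content removed 15 of the 16 rose, with a median of 1.15. A trend with message length itself is not removed in this way. The median was smaller under quantile normalization, at 0.35 with 11 of the 16 called higher, and at equal FPKM totals, at 0.61 with 15. Of 13 mitochondrially encoded genes 7 rose and 1 fell, the same as adjusted over the list alone. Camera gave them an adjusted p of 0.018, but adjusted p = 0.58 with an estimated correlation. The 13 genes took 8.22 and 10.8% of reads in the printed libraries and 6.45 to 6.96% in M14A plate. The cytochrome c oxidase subunits MT-CO2 (from 10879 ± 1725 to 31587 ± 944 FPKM) and MT-CO3 (log2 fold change 1.18, SE 0.13) rose most, and MT-ND5 fell (log2 fold change -0.85, SE 0.18). MT-CO2 and MT-CO3 lost their calls under quantile normalization (log2 fold change 0.10 and 0) and with no filter (limma adjusted p = 0.067 and 0.092). Quantile normalization gives every library the same values rank by rank, which leaves the most abundant genes little room to differ. The list call was lost without printed library 2 (camera adjusted p = 0.13), with a filter at 5 FPKM (0.097), with the trend removed (0.42) and with that and M14A plate library 1 left out (0.080), and turned to lower under quantile normalization (0.0095). Of 7 replication-dependent histone genes 5 rose and 0 fell (6 and 0 adjusted over the list alone). Their camera adjusted p was 0.0029, but adjusted p = 0.37 with an estimated correlation. HIST1H1C rose from 85.5 ± 11.6 to 193 ± 26.7 FPKM, and HIST1H2BK from 96.7 ± 7.67 to 177 ± 17.7 FPKM. The call of HIST1H2BK was lost under quantile normalization (log2 fold change 0.17) and at equal FPKM totals (0.11). The histone list lost its call with the length and GC trend removed and M14A plate library 1 left out (camera adjusted p = 0.065).

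Of 13 hepatocyte secreted proteins 8 rose and 0 fell (9 and 0 adjusted over the list alone). The camera adjusted p was 0.0016, but adjusted p = 0.29 with an estimated correlation. The apolipoprotein APOC3 rose from 19.4 ± 5.69 to 77.6 ± 3.94 FPKM (log2 fold change 1.99, SE 0.23, adjusted p = 9.4e-04). ALB, the main plasma protein, rose from 26.3 ± 3.01 to 81.2 ± 2.97 FPKM (log2 fold change 1.59, SE 0.14, adjusted p = 5.3e-04). Without printed library 2, 5 of the 13 rose, and under quantile normalization the list was not called (camera adjusted p = 0.071). Liver transcription factors other than HNF4A went the other way, with 1 of 10 rising and 5 falling (1 and 7 adjusted over the list alone). For these the camera adjusted p was 0.023, but adjusted p = 0.58 with an estimated correlation. CEBPB, a factor of the acute phase, fell from 191 ± 60.1 to 83.7 ± 29.8 FPKM (log2 fold change -1.19, SE 0.28, adjusted p = 0.012). The zinc finger factor GATA4 fell from 7.38 ± 3.005 to 3.22 ± 1.18 FPKM (log2 fold change -0.96, SE 0.28, adjusted p = 0.028). Both calls were lost without printed library 2 (log2 fold change -0.82 and -0.67), and the list then had a camera adjusted p of 0.098 with 1 member lower. The list was not called without M14A plate library 1 (0.15) or with a filter at 5 FPKM (0.097) either.

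The other lists were not called in the main fit, although several passed under other settings. Of 15 hypoxia and glycolysis genes 6 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.05004). Among them CA9 rose from 51.3 ± 18.6 to 190.3 ± 48.8 FPKM (log2 fold change 1.90, SE 0.27, adjusted p = 0.0017), and the mitophagy receptor BNIP3 from 32.1 ± 6.22 to 76.2 ± 0.516 FPKM (log2 fold change 1.24, SE 0.17, adjusted p = 0.0014). The list passed the test without M14A plate library 1 (11 rose and 2 fell, camera adjusted p = 0.0016) and without HepaRG plate library 1, 2 or 3 (0.048, 0.048 and 0.047). With an estimated correlation, over all libraries, its adjusted p was 0.65. Of 13 immediate early genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.75), with a median log2 fold change of -0.19 and a mean of 0.40. Beside FOS and FOSB, ATF3 (log2 fold change 1.25, SE 0.22) and NR4A1 (0.64, SE 0.15) rose, while JUNB (-1.02, SE 0.25), DUSP1 (-0.75, SE 0.21) and KLF6 (-1.39, SE 0.16) fell. Of 13 NF-kappaB and acute phase genes 7 rose and 2 fell, the same as adjusted over the list alone (camera adjusted p = 0.13). Serum amyloid SAA1, which has a close paralog, rose from 1005 ± 79.8 to 2559 ± 179 FPKM. NFKBIA, the inhibitor and early target of NF-kappaB, fell from 126 ± 28.6 to 39.9 ± 2.45 FPKM (log2 fold change -1.62, SE 0.18, adjusted p = 8.6e-04). Of 14 p53 and DNA damage genes 6 rose and 0 fell, the same as adjusted over the list alone (camera adjusted p = 0.070). Among these GADD45B rose from 29.5 ± 5.67 to 70.4 ± 3.92 FPKM, and PMAIP1 from 6.93 ± 1.40 to 15.95 ± 3.32 FPKM. The call of PMAIP1 was lost at equal FPKM totals (log2 fold change 0.39) and at equal totals without mitochondrial genes (0.56). With no filter the p53 list (0.0053) and the NF-kappaB list (0.017) passed as higher, and with an estimated correlation in the main fit each had an adjusted p of 0.37. Of 12 NRF2 genes 4 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 0.56). Ferritin light chain FTL rose from 4792 ± 845 to 12750.2 ± 1564 FPKM. Thioredoxin TXN rose from 335 ± 31.9 to 691 ± 39.1 FPKM, with a turned sign under quantile normalization (-0.062). Of 13 heat shock genes 2 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.28). The chaperonin HSPE1 rose from 21.1 ± 0.808 to 47.2 ± 1.44 FPKM, and the call of HSPB1 (log2 fold change 0.86, SE 0.25) was lost with any library other than M14A plate library 1 left out. Of 12 endoplasmic reticulum stress genes 1 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 0.56). ATF4 rose from 50.3 ± 11.2 to 105 ± 7.96 FPKM. CHAC1 fell (log2 fold change -0.81, SE 0.22), a call lost without M14A plate library 2 or printed library 2 (-0.80 and -0.61).

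Of 19 G2/M genes 1 rose and 3 fell, the same as adjusted over the list alone (camera adjusted p = 0.093). The proliferation marker MKI67 fell from 14.8 ± 5.40 to 4.30 ± 1.93 FPKM, and TOP2A from 18.5 ± 7.18 to 6.88 ± 1.10 FPKM. Without printed library 1 neither was called (log2 fold change -1.17 and -1.09), and without printed library 2 TOP2A was not (-1.37). With the length and GC trend removed 9 members fell and the list passed the test (camera adjusted p = 0.0058). With an estimated correlation and the trend left in, the adjusted p of this list was 0.37. Of 17 DNA replication genes 1 rose and 4 fell, the same as adjusted over the list alone (camera adjusted p = 0.30). The flap endonuclease FEN1 fell from 58.9 ± 10.7 to 30.4 ± 1.62 FPKM. The rise, in GINS2, lost its call without printed library 1 (log2 fold change 0.39), M14A plate library 2 (0.45) or HepaRG plate library 3 (0.53). The replication list passed as lower under quantile normalization (0.016), at equal FPKM totals (0.024) and at equal totals without mitochondrial genes (0.038), and its adjusted p with an estimated correlation in the main fit was 0.57. Of 14 extracellular matrix and mesenchymal genes 2 rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.24). The transcriptional repressor SNAI1 rose from 0.300 ± 0.127 to 3.66 ± 0.212 FPKM (log2 fold change 1.85, SE 0.13, adjusted p = 3.6e-04). Fibronectin FN1 fell from 181 ± 28.9 to 88.3 ± 19.3 FPKM (log2 fold change -1.03, SE 0.19, adjusted p = 0.0046). Of 15 adhesion and YAP target genes 1 rose and 4 fell, the same as adjusted over the list alone (camera adjusted p = 0.56). The YAP target AMOTL2 fell from 34.5 ± 10.96 to 11.98 ± 1.46 FPKM (log2 fold change -1.41, SE 0.23, adjusted p = 0.0027). The fall of vinculin (VCL) was not called without printed library 1 (log2 fold change -0.49), M14A plate library 2 (-0.74) or HepaRG plate library 1, 2 or 3 (-0.69), or with the length and GC trend removed (-0.41). Of 14 sterol synthesis genes 0 rose and 2 fell, the same as adjusted over the list alone (camera adjusted p = 0.59). Of 7 stellate cell and fibroblast markers 2 rose and 0 fell, the same as adjusted over the list alone (camera adjusted p = 0.27). Under quantile normalization the adhesion (0.0017) and sterol (0.019) lists passed as lower, with adjusted p = 0.65 and 0.69 by an estimated correlation in the main fit. Of the sterol and stellate calls, SQLE, DES and DCN were lost without printed library 1 (log2 fold change -0.54, 0.76 and 0.91). Without printed library 2, SQLE and DCN were not called (-0.70 and 0.89), and SQLE and DCN were not called with HepaRG plate library 1, 2 or 3 left out, at unaltered values of -0.62 and 0.90.

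Of 10 drug metabolism enzymes 4 rose and 0 fell (camera adjusted p = 0.30), among them GSTA1 from 6.55 ± 1.32 to 20.2 ± 4.66 FPKM. For the urea cycle and ammonia handling 2 of 6 rose and 0 fell (camera adjusted p = 0.56), among them the argininosuccinate synthase ASS1 from 107 ± 18.7 to 191 ± 5.16 FPKM. For bile acid synthesis and transport 1 of 8 rose and 0 fell (camera adjusted p = 0.57), the sterol hydroxylase CYP27A1 from 29.1 ± 1.00 to 49.3 ± 6.25 FPKM. The other urea cycle rise, in ASL, lost its call with any library other than M14A plate library 1 left out (adjusted p = 0.068 to 0.24) and with the replicate number as a block (0.078). The counts adjusted over the list alone were the same for these 3 lists. At equal FPKM totals the calls of ASS1 (log2 fold change 0.088) and CYP27A1 (-0.0099) were lost. For gluconeogenesis and glycogen 1 of 3 rose and 0 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.60). This rise, in PYGL, lost its call without printed library 1 (adjusted p = 0.0502) or 2 (0.12), without M14A plate library 2 (0.071) and with the replicate number as a block (0.061). Of 8 biliary and progenitor markers 1 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 0.89, direction lower, around a median log2 fold change of 0.0042 and a mean of 0.039). The biliary keratin KRT7 rose from 2.03 ± 0.202 to 5.74 ± 1.30 FPKM, and the transcription factor SOX4 fell from 5.69 ± 0.206 to 1.88 ± 0.186 FPKM. KDR stood at 1.10 ± 0.245 FPKM and LAPTM5 at 5.96 ± 1.11 FPKM in printed cells, and 0 endothelial and 0 leukocyte markers were called, also when adjusted over the list alone. LAPTM5 passed as higher without M14A plate library 1 (log2 fold change 0.51). KDR passed as lower at equal FPKM totals (-0.59) and at equal totals without mitochondrial genes (-0.50).

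In total 2544 genes were higher and 2226 lower in printed than in plate M14A cells, 713 and 650 by at least 2-fold. Of the 4 lists called higher and 1 called lower, 0 calls held with an estimated correlation. These directions are relative to the deposited scaling. At equal FPKM totals the median log2 fold change of all genes moved from 0.01 to -0.51, with 494 genes higher and 6613 lower (6.95 against 53.3% of calls higher). At equal totals without mitochondrial genes it moved to -0.39, with 817 higher and 5357 lower (13.2%). At equal FPKM totals 15 of the 16 ribosomal protein genes still rose, hepatocyte secreted proteins had 5 higher and 2 lower, and hypoxia genes 2 higher and 5 lower. The counts of genes were 1202 and 1378 without printed library 1, 1590 and 1228 without printed library 2, and 4045 and 3866 without M14A plate library 1.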

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

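The alternatives with the length and GC trend removed, with that and M14A plate library 1 left out, and with protein-coding genes only were chosen after the data were seen. Over all 24 alternatives, 1052 of the list results kept direction and side of the threshold, 33 gained and 15 lost a call and 2 turned. Of the named genes' results 2482 kept both, 12 gained and 168 lost a call and 12 turned. HNF4A kept its calls throughout, with a log2 fold change of 2.50 to 2.61 (M14A plate minus HepaRG plate) and -1.52 to -1.21 (M14A printed minus M14A plate) over the libraries left out in turn. Counts of genes higher and lower in M14A plate than in HepaRG plate were 1393 and 948 with a filter at 5 FPKM (fewer genes tested) and 1460 and 1084 at adjusted p below 0.01, the lower count was 3376 at equal FPKM totals and 3856 with the trend removed and M14A plate library 1 left out, and with a library left out the counts ranged from 1567 to 2912 and from 1252 to 3220. Counts for M14A printed minus M14A plate were 1260 lower with the filter at 5 FPKM, 494 higher and 6613 lower at equal FPKM totals, 817 and 5357 at equal totals without mitochondrial genes, 1062 and 954 with only the 2 groups compared (fewer samples), 1265 and 1103 at adjusted p below 0.01, and 4485 and 3773 with the trend removed and library 1 left out; with a library left out they ranged from 1202 to 4045 and from 1228 to 3866. Where a printed library is left out, the lone sample is assumed to vary like the other groups. The log2 fold change of FOXM1 between the flask-grown lines passed the threshold at -0.38 with median-ratio rescaling, -0.43 with quantile normalization, -0.54 at equal FPKM totals, -0.47 at equal totals without mitochondrial genes, -0.43 with the trend removed and -0.50 with that and library 1 left out, and ranged from -0.48 to -0.23 with a library left out. Between printed and plate cells FOXM1 passed the threshold at the 2 equal totals, at -0.75 and -0.59, ranged from -0.19 to 0.060 with a library left out, and was 0.038 with the trend removed and library 1 left out. In printed cells the hypoxia list also passed as higher with no filter (camera adjusted p = 0.0053), with median-ratio rescaling (0.035), at equal FPKM totals (0.017), at equal totals without mitochondrial genes (0.014), with voom weights (0.037), with protein-coding genes only (0.049), with the trend removed (0.012) and with that and library 1 left out (4.1e-04). Camera compares a list with the other genes: at equal FPKM totals the hypoxia list had 2 members called higher and 5 lower, with a median log2 fold change of 0.090 against -0.51 over all genes, so it was higher only relative to them. The G2/M list also passed as lower with a filter at 5 FPKM (0.047), under quantile normalization (0.013), at equal FPKM totals (0.029), at equal totals without mitochondrial genes (0.046) and with the trend removed and library 1 left out (0.0039). Under quantile normalization, the ribosomal protein list turned lower in M14A plate against HepaRG plate (camera adjusted p = 0.010), the mitochondrially encoded list turned lower in printed cells (0.0095), and HSPB1 (-0.081) and TXN (-0.062) turned sign in printed cells. For the ribosomal protein list in M14A plate against HepaRG plate, camera with an estimated correlation gave an adjusted p of 0.90 in the main fit. In printed cells, at equal FPKM totals the log2 fold changes of ASL (-0.20), CYP27A1 (-0.0099), PYGL (-0.21), GINS2 (-0.15) and LAPTM5 (-0.25) turned, and at equal totals without mitochondrial genes those of ASL (-0.035), PYGL (-0.030) and LAPTM5 (-0.11). The equal totals shift all genes of a library by the same factor, by construction. Quantile normalization gives every library the same values rank by rank. Genes near the top rank in every library, such as MT-CO2 and MT-CO3, then have little room to differ, also by construction. For the other changes the cause was not tested. The labels give replicates only a number, and deviations of same-numbered HepaRG and M14A plate libraries correlated at -0.07, 0.08 and -0.16. Those of same-numbered M14A plate and printed libraries correlated at 0.49 and 0.36, but plate library 3 and printed library 2, of unlike numbers, at 0.43, and with 2 printed libraries the deviations mirror each other. With the replicate number as a block, 2257 and 2162 genes were called in M14A plate against HepaRG plate and 2286 and 2094 in printed against plate cells.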

Other observations

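The genes and families below were picked after their values were seen, and the tests of RNA mixed in from printed cells, of a mislabelled library and of the zf-C2H2 family were chosen only after the result was seen. Some genes were on in only 1 of the 2 flask-grown lines. With a mean of at least 5 FPKM in one line and below 0.5 FPKM in every library of the other, 34 genes were seen in HepaRG plate only (27 protein-coding) and 48 in M14A plate only (37 protein-coding). Those on in HepaRG included the collagenase MMP2, the ketone body enzyme OXCT1, and the cytidine deaminase APOBEC3B, beside NQO1, MAGEC2 and COL5A1. Those on in M14A included the trefoil peptide TFF3, the cancer-testis gene MAGEB1, the imprinted gene NDN, the carboxypeptidase CPB2 and the growth factor CSF3, beside LCN2. All 48 genes of the M14A group were at or above 0.5 FPKM in both printed libraries. Several abundant products of mature hepatocytes had low values everywhere: over the 8 libraries the highest value was 0.283 FPKM for TTR, 0.325 for TF, 0.521 for HP, 0.0635 for AHSG and 0.471 for CYP3A4. VIM, the intermediate filament of mesenchymal cells, reached at most 0.12 FPKM, with 24.4% of its exon bases in other genes. Low values were also seen for EIF4A1, a translation factor of all cells, at 0.478 to 1.32 FPKM with 48.6% of its exon bases in other genes, and the reason was not tested. The ferritin gene FTH1, with 62.4% in another gene, stood at 928 to 2119 FPKM, and TTR and HP have 0% in other genes. The cyclin gene CCNB2 also has 0% in other genes and reached at most 0.436 FPKM, while CCNB1 stood at 36.5 to 66.7 FPKM. An overlap of 0% therefore does not show that a low value is a silent gene.

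Families of transcription factors, as the deposited annotation gives them, were also compared in printed against plate M14A cells. Of 343 tested zf-C2H2 genes 5 rose and 119 fell (camera adjusted p = 4.6e-12 over 10 families, and 0.021 as adjusted p with an estimated correlation), and of 35 ZBTB genes 0 rose and 17 fell (1.4e-06, and 0.019 as adjusted p with an estimated correlation). Forkhead genes had 0 rises and 10 falls of 20 (7.6e-06, but adjusted p = 0.11 with an estimated correlation) and homeobox genes 3 and 13 of 46 (0.0029, but adjusted p = 0.17 with an estimated correlation). In M14A plate against HepaRG plate, zf-C2H2 genes had the lowest camera adjusted p of the families (0.057, with 23 higher and 64 lower), and none passed the test.

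In printed cells ribosomal protein genes rose and long genes fell together. A trend between libraries in gene length and GC content was tested as the whole cause. With it removed, 15 of the 16 ribosomal protein genes were still called higher, with a median log2 fold change of 1.15 against 1.37 before. Of the genes at least 2-fold lower 68.4% (444 of 649) stayed so. The average trend was small beside these changes, with medians from 0.45 to -0.26 over the quintiles of length and 0.07 to -0.05 over the lowest and highest of GC. Removing it could therefore hardly have undone them. Both values argue only against this average trend, with length and GC added together, as the whole cause. Effects of length and GC acting jointly, or stronger in some genes than the average, are not reached. Gene length counts all exonic bases, 5894 for RPS3, so a trend with message length is not reached and stays open. For the zf-C2H2 genes, which had a median of -0.38, 10000 random gene sets matched to 342 of them on gene length, GC content and expression had medians around -0.076. A share of 1e-04 was as low, the smallest that these draws can give, which argues against these properties as the whole cause. Genes of random sets need not move together as those of a family can, so this share can overstate the evidence. Message length was not matched. A loss of short-lived messages, many of which encode transcription factors, is a candidate explanation that goes with the falls of HNF4A and NFKBIA but was not tested, and FOS rose. Freezing and grinding, time in the bioink and printing differ together from flask culture, so their parts cannot be told apart.

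M14A plate library 1 differed from the mean of libraries 2 and 3 by a spread over genes 2.17 times that between libraries 2 and 3. Averaging lowers the first spread, so with equal noise in each library it would be the smaller of these spreads. The bounds below were set without regard to this. With the GC and length trend removed the ratio was 1.65, between the bounds set for a trend as the cause and against it, so how far GC content accounts for it stays open. Whether RNA of printed cells was mixed into this library also stays open. With the trend removed, its median share of the way toward the printed level was -0.204 over 54 genes at least 4-fold lower in printed cells (quartiles -0.417 and 0.228) and 0.0632 over 35 genes at least 4-fold higher (0.00266 and 0.206), so the lower genes spread to both sides of 0. A difference of the culture itself may remain, and was not tested.

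For the 34 genes seen in HepaRG only, loss of chromosomal regions in M14A was examined in their 230 expressed neighbours within 500 kb. A loss would take the neighbours along, but their median log2 fold change was -0.16 (lower quartile -0.62). This argues against large regional losses as the cause for most of the 34 genes. The neighbours of all these genes were pooled, so losses at some of the places are not reached by this test. Losses confined to single genes, or smaller than the window, are not reached either. The separately collected printed M14A cells held these genes at a median of 0.556% of the HepaRG mean. Of the 34 genes, 27 were below 0.5 FPKM in both printed libraries. This argues against a swap of labels between the whole M14A plate and HepaRG plate groups. The genes were selected as low in every M14A plate library, so a single swapped library there is not what this compares. Whether the HepaRG libraries come from the parent line is not reached. A switch of gene activity in the edited line, growth from few founder cells of HepaRG, or a separate origin of the cells may account for these genes. Sequence variants, which would separate these explanations, were not analysed here.

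The 6 flask-grown libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, called as many as 4429 genes, and the highest other split called 0; for calls of at least 2-fold it was also 1, with 1547 genes against 0. At an unadjusted limma p below 0.05 the real split had 6093 genes and the others 97 to 370. Each other split mixes both lines within its groups, so the difference between the lines enters the spread. Few calls are then left by construction, and these counts do not measure how many calls arise by chance.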
